A study of Homo sapiens with 16 samples.

How the data were processed

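Gene expression was measured in 16 samples of PNT1A, an immortalised line of human prostate epithelial cells, with 1 array per sample. Per the labels, cells were grown with serum and then kept for 48 h with 1% DMSO as vehicle or with MEHP, BDB or DOS at a concentration of 1e-04 M, and each of these 4 groups has 4 samples. A share of DMSO is recorded for the DMSO samples and not for the treated ones. Total RNA (25 ng) was labelled with Cy3 and hybridised to Agilent arrays. The labels give no further names for BDB and DOS, so both keep their abbreviations. They do not say whether the replicates of a group came from separate cultures, so the p-values measure the spread between these samples and nothing wider. The title of the series and the titles of the 4 DMSO samples carry the note set2, which the titles of the treated samples lack.

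Per the file headers, the scanner files were made with Agilent Feature Extraction 11.5.1.1, and their processed signal is an intensity on a linear scale, with the background subtracted and spatial trends removed within each array, not scaled between arrays. The deposited files also hold flags of 0 or 1 per spot, of another kind than an intensity (other). The deposited table of the series holds log2 values of 27203 probes, made by the authors with a method that the labels do not give. Its columns have medians from 7.96 to 8.00, correlate with the log2 median spot intensities of the same arrays at 0.9996 to 0.9999, and leave 0 columns without a sample. The arrays were annotated on an older genome build than the RefSeq table used here (GRCh38.p14), so no coordinates are given.

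Each array carried 58717 spots other than controls, for 42405 distinct probes. Spots that the scanner software marked as not uniform or as outliers, 299 to 472 per array, were left out, which removed 60 probes altogether. Spots of 1 probe were averaged, log2 values were taken, and the 75th percentile of each array was subtracted. Before that step the 75th percentile ranged from 630.6 to 853.3 between arrays and the median signal from 60.1 to 87.5. Between 25386 and 28189 probes per array (60.0 to 66.6%) were well above background, and 0 spots were saturated. RefSeq symbols were found for 26364 probes, among them 26361 of the 27244 probes with a RefSeq transcript. A gene was represented by its brightest probe over all 16 arrays and was tested if that probe was well above background on all 4 arrays of at least 1 group, which left 20893 genes. The number of arrays limits the precision, and the median SE of a log2 difference was 0.166.

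Groups were compared with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8). All 16 arrays entered a single fit with 12 residual degrees of freedom and 2.93 prior degrees of freedom. Each compound was compared with DMSO and with both other compounds, which makes 6 comparisons. P-values are two-sided and were adjusted over the genes tested with the Benjamini-Hochberg method, with a threshold of 0.05. The same fit was tested on simulated data with 20893 genes, of which 50 were given each size of change. With MEHP against DMSO it called 22% of the genes changed by 0.5 on the log2 scale, 88% of those changed by 1 and 100% of those changed by 1.5 or 2, and 7 of 20643 unchanged genes. Without simulated changes, DOS against DMSO gave 0 calls. The simulated noise was normal and independent between genes, at each gene's spread in the fit, with no slide effect. Changed genes were drawn from those brighter than the median, so the shares called may be higher than in the real data.

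Before the data were examined, 34 gene lists were fixed: pathways that plasticizers or stress can touch and markers of cell types, prostate epithelium among them. Their shifts were tested with limma's camera at a preset correlation between genes of 0.01, and adjusted over 102 tests against DMSO and over 102 tests between compounds. Beside it stand camera with a correlation estimated from the data, and fry. A list score is the mean over the list's genes of the log2 signal, each gene centred on its mean over the 16 arrays, and scores were compared with an exact two-sided permutation test, whose smallest possible p for 4 against 4 arrays is 0.0286. After adjustment the smallest exact p was 0.265 against DMSO and 0.416 between compounds, so no list passed that test. With only 11 and 7 tests at the smallest possible p, none could pass after adjustment over 102. The adjusted test therefore cannot decide about a single list, and the exact p-values given below are unadjusted. Intervals of score differences come from a linear model of the scores of all 16 arrays. The same early plan set which genes are named. These are, in each comparison with DMSO, up to 10 raised and 10 lowered genes with the largest changes among those past the threshold whose groups do not overlap, and up to 2 raised and 2 lowered members of each list. The genes named whatever their values include PDK4, ANGPTL4, CPT1A, PLIN2, HMGCS1, HMOX1, CYP1A1, CYP1B1, DDIT3, CDKN1A and MKI67, and also the 10 genes with the smallest p where fewer than 10 pass. Between compounds up to 3 genes are named in each direction. Members of a list that passed when adjusted over the list alone are also named as examples, chosen after their values were seen.

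The arrays came on 3 slides that do not match the groups. Slide 1 held 1 DMSO, 2 MEHP, 3 BDB and 1 DOS sample, slide 2 held 1 DMSO, 1 MEHP, 1 BDB and 2 DOS samples, and slide 3 held 2 DMSO, 1 MEHP and 1 DOS sample and 0 BDB samples. Alternatives tried were normexp background correction (offset 50), quantile or median scaling, the deposited table, no filter or a filter on all 16 arrays, slide as a fixed or random block, a replicate block, fits of 2 groups only, an intensity trend with robust variances, array weights, the mean over a gene's probes, every probe by itself, thresholds with a 1.5-fold change, and leaving out each array in turn. The files hold no mean spot signal, so normexp was run on the median spot signal. After the data had been seen, fits without slide 2 and fits without the second DMSO sample with slide as a block were added.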

Results

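Gene expression was profiled in PNT1A cells, an immortalised line of human prostate epithelium that is not cancerous, after 48 h with 1 of 3 compounds at 1e-04 M or with the vehicle, 1% DMSO. The series is described as a screen of green plasticizers. There were 4 samples in each of the groups DMSO, MEHP, BDB and DOS, and 20893 genes were bright enough to be tested. Between 60.0 and 66.6% of the probes lay well above background on an array. The first principal component held 36.4% of the variance and separated slides (R² = 0.899) more than groups (R² = 0.0815), with the 5 arrays of slide 2 between 26.8 and 62.0 and the other 11 between -36.8 and -0.57. Pairs of arrays of the same group correlated at 0.977 to 0.995 across genes, which are not independent replicates.

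The comparison of MEHP with DMSO asked which genes a phthalate metabolite changes in prostate cells. MEHP, mono-(2-ethylhexyl) phthalate, is the monoester formed from the plasticizer DEHP in the body. ANGPTL4 (NM_139314), a secreted inhibitor of lipoprotein lipase, rose 16.7-fold (95% interval 11.1 to 25.2), by 4.06 ± 0.28 on the log2 scale (SE of the limma fit, n = 4 per group, adjusted p = 6.34e-06). PDK4 (NM_002612), a mitochondrial kinase that restrains pyruvate oxidation, rose 4.04-fold (2.73 to 5.97, log2 2.01 ± 0.27, adjusted p = 0.0118). SLC25A20 (NM_000387), the carrier that brings acylcarnitines into mitochondria, rose 2.04-fold (1.68 to 2.49, log2 1.03 ± 0.13, adjusted p = 0.0118). ACADVL (NM_000018), which opens the beta-oxidation of very long fatty acids, rose 1.82-fold (1.49 to 2.22, log2 0.86 ± 0.13, adjusted p = 0.0429). PLIN2 (NM_001122), a coat protein of lipid droplets, rose 1.51-fold (1.32 to 1.74, log2 0.60 ± 0.09, adjusted p = 0.0429). CYP26A1 (NM_057157), an enzyme that breaks down retinoic acid, was 7.01-fold lower (3.95 to 12.4, log2 -2.81 ± 0.39, adjusted p = 0.0152).

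These 6 genes, 5 raised and 1 lowered, were the ones that passed among 20893 tested with limma, and in each of them the 4 MEHP arrays lay apart from the 4 DMSO arrays. An unadjusted p under 0.05 was reached by 876 genes, where chance gives about 1045, and 596 genes (2.85%) had groups that did not overlap, where chance gives 2.86%. Within slides 1, 2 and 3 the log2 change of ANGPTL4 was 4.08, 4.12 and 3.76, that of PDK4 2.06, 2.80 and 1.36, and that of SLC25A20 1.04, 1.16 and 0.94. For ACADVL the values were 0.86, 0.87 and 0.69, for PLIN2 0.56, 0.74 and 0.51, and for CYP26A1 -3.16, -4.02 and -1.77. With slide as a fixed block 10 genes passed, these 6 among them, with adjusted p-values of 3.02e-05 for ANGPTL4, 0.0120 for PDK4, SLC25A20, ACADVL and CYP26A1, and 0.0207 for PLIN2. Without the first DMSO array 1 gene passed, ANGPTL4, and ACADVL and PLIN2 passed in 2 of the 16 fits that left out 1 array. Over all the fits tried the log2 change ranged from 3.52 to 4.16 for ANGPTL4, 0.86 to 2.21 for PDK4 and 0.68 to 1.09 for SLC25A20. It ranged from 0.81 to 0.93 for ACADVL, 0.41 to 0.66 for PLIN2 and -3.06 to -2.03 for CYP26A1.

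**Figure D1:**
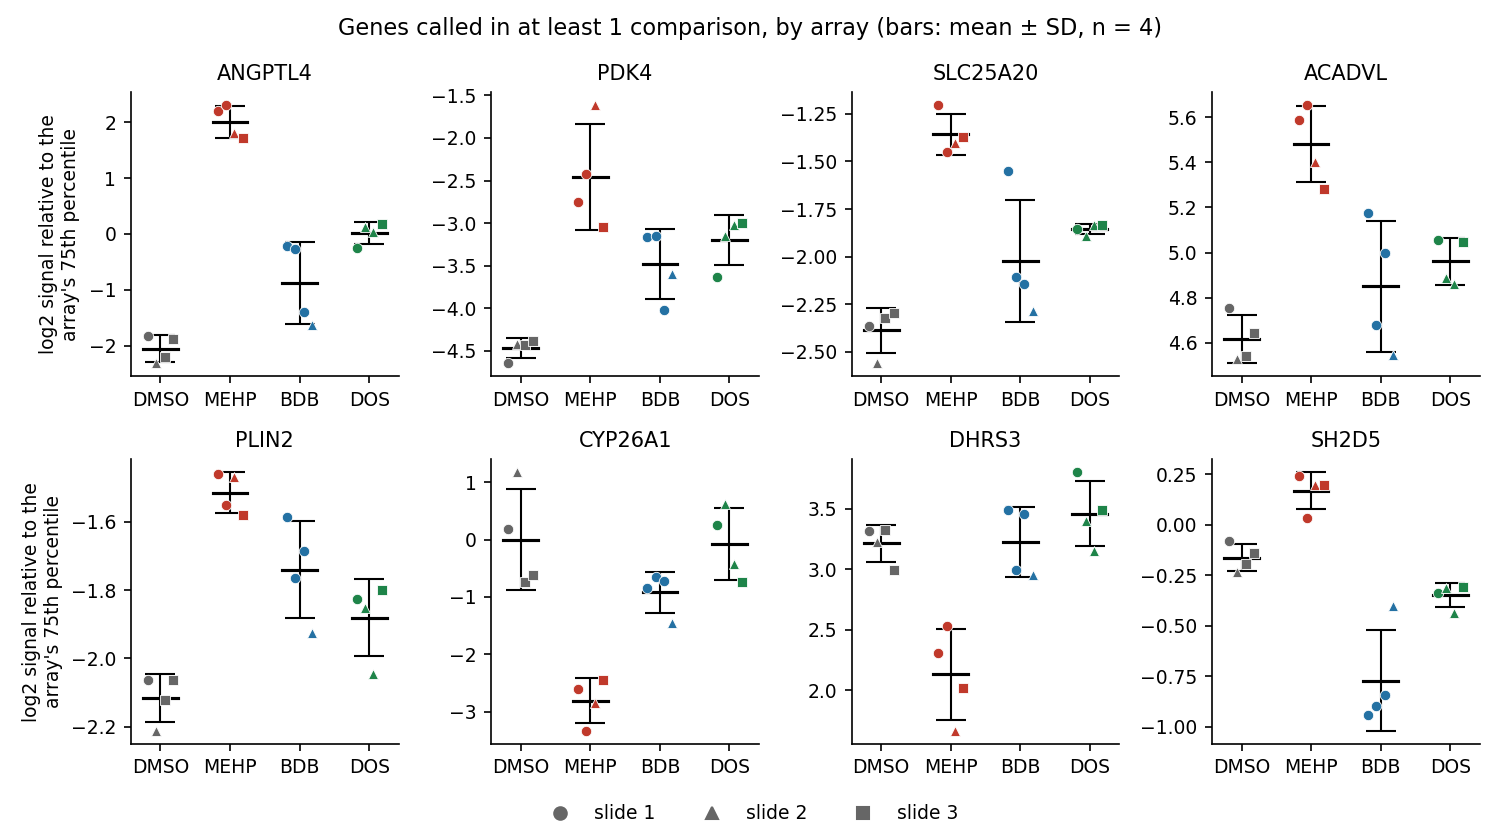
Log2 signal relative to the 75th percentile of each array (y axis) for 8 genes in DMSO, MEHP, BDB and DOS. Dots are arrays, the marker gives the slide, and bars are the mean ± SD (n = 4). ANGPTL4 lay between -2.31 and -1.82 in DMSO and between 1.72 and 2.31 in MEHP, and CYP26A1 between -0.74 and 1.17 in DMSO and between -3.33 and -2.45 in MEHP.

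ACAA2, CPT1A, NTF3 and DHRS3 came next to the threshold in MEHP without passing it. ACAA2, the last enzyme of a beta-oxidation cycle, had a log2 change of 0.76 ± 0.13 (adjusted p = 0.0747), and CPT1A, the gatekeeper of fatty acid entry into mitochondria, 1.09 ± 0.19 (adjusted p = 0.0850). NTF3, a neurotrophin, had 1.13 ± 0.20 (adjusted p = 0.0850), and DHRS3, a retinaldehyde reductase, -1.08 ± 0.19 (adjusted p = 0.0978). With slide as a block CPT1A (1.08 ± 0.14, adjusted p = 0.0123) and DHRS3 (-1.16 ± 0.14, adjusted p = 0.0120) passed, and ACAA2 and NTF3 did not (0.0872 and 0.108). The dioxin-responsive enzymes CYP1A1 and CYP1B1 had log2 changes of 0.96 ± 0.28 and 0.67 ± 0.18 (adjusted p = 0.771 and 0.619). Other genes named in advance had log2 values of 0.29 for HMOX1, 0.85 for DDIT3 (0.19 without the second DMSO sample), 0.43 for CDKN1A, -0.25 for MKI67 and -0.27 for HMGCS1, none of which passed.

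PPAR targets, genes that the nuclear receptors for fatty acids switch on, were the list with the clearest shift in MEHP. Of its 24 tested genes 5 were raised over all genes tested, and 9 were raised and 1 lowered when adjusted over the list alone. Beyond those 5, the genes raised over the list alone were CPT1A, ACAA2, ECH1 (log2 0.65) and ETFDH (0.50), which act in fatty acid oxidation, and the lowered one was TXNIP (-0.49), a thioredoxin-binding protein. Other members that act there, named after their values were seen, did not pass, with log2 values of 0.08 for HADHB, 0.06 for HADHA, 0.02 for ACAA1, -0.0038 for CPT2 and -0.11 for ACADM. The mean log2 change of the list was 0.48 (interval of the score 0.37 to 0.59) and its median 0.17, with an exact p of 0.0286, and within slides 1, 2 and 3 the scores differed by 0.46, 0.59 and 0.39. With slide as a block the mean was also 0.48. The list passed with an adjusted p of 0.0278 with an estimated correlation, the 1 call of 102 that did so, and with fry (adjusted p = 0.000532).

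**Figure D2:**
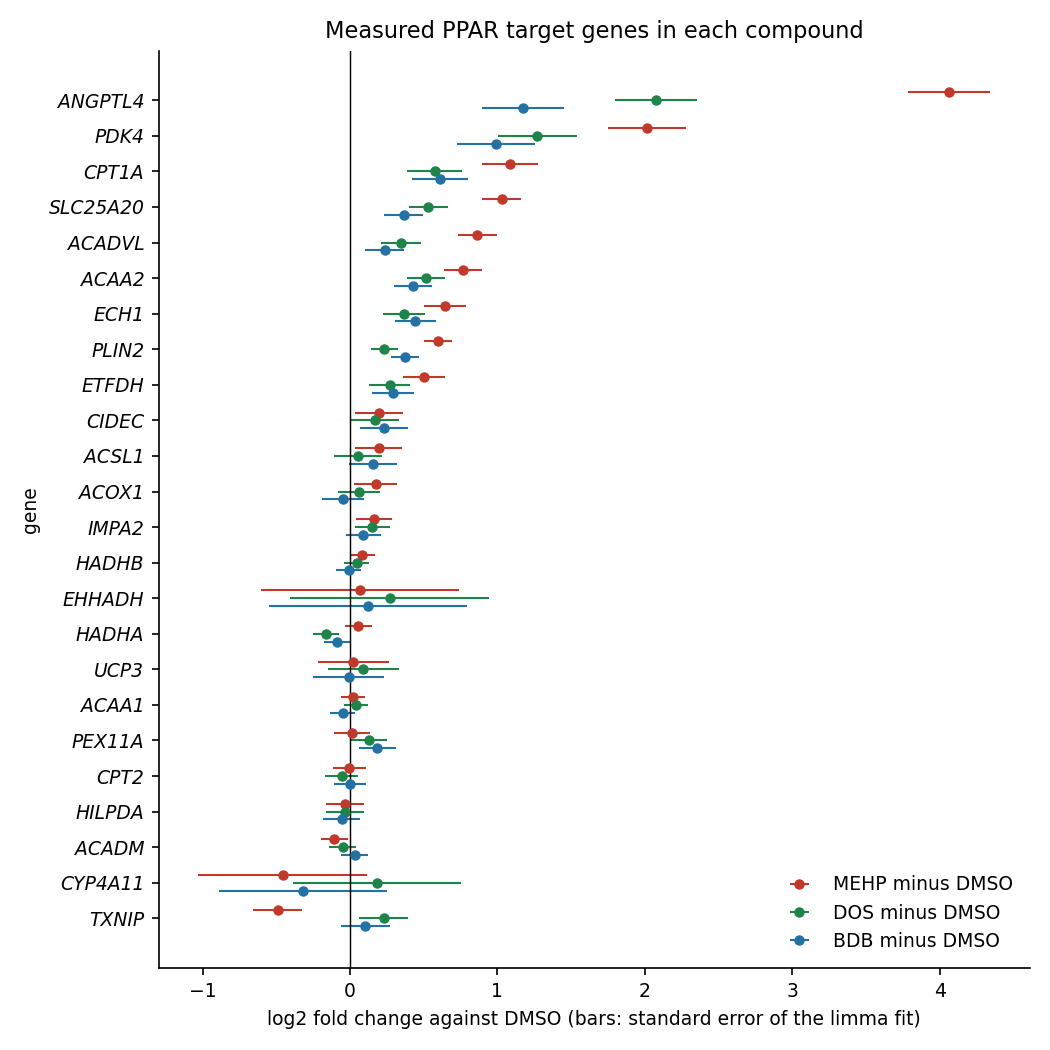
Log2 fold change against DMSO (x axis) of the 24 tested PPAR target genes (y axis) in MEHP, DOS and BDB, with the SE of the limma fit (n = 4 per group). ANGPTL4 stood at 4.06 in MEHP, 2.08 in DOS and 1.18 in BDB, and PDK4 at 2.01, 1.27 and 0.99.

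At the preset correlation camera called 14 further lists in MEHP, none of which kept the call with an estimated correlation. Prostate luminal epithelium markers had a mean log2 change of -0.43 (adjusted p = 0.110 with an estimated correlation, exact p = 0.0286), and within slides 1, 2 and 3 the score differed by -0.45, -0.77 and -0.19. Of 12 tested genes 0 were lowered over all genes tested and 1 when adjusted over the list alone, FOXA1 (log2 -0.73), a pioneer factor of the luminal lineage. The second DMSO sample scored 0.68 on this list and the other DMSO samples 0.00 to 0.17, and without that sample the mean was -0.28. Aryl hydrocarbon receptor targets had a mean of 0.23 (adjusted p = 0.110 with an estimated correlation). Of 8 genes 0 were raised over all genes tested and 3 when adjusted over the list alone: CYP1A1, CYP1B1 and TIPARP (log2 0.66), a repressor of that receptor. Within slides 1, 2 and 3 that score differed by 0.48, 0.10 and 0.20. The first DMSO sample, on slide 1, scored -0.40 on this list and the other DMSO samples -0.08 to 0.09. Hypoxia and glycolysis genes had a mean of -0.20 (adjusted p = 0.378 with an estimated correlation), with 0 lowered over all genes tested and 1 of 34 when adjusted over the list alone, CA9 (log2 -2.44), a carbonic anhydrase.

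The amino acid response and ATF4 targets had a mean of 0.51 in MEHP (adjusted p = 0.391 with an estimated correlation). Of 32 genes 0 passed over all genes tested or over the list alone, and the score of the second DMSO sample was -1.65 against a mean of 0.05 in the other DMSO samples. Within slides 1, 2 and 3 the score differed by 0.19, 1.60 and 0.04, and without that sample the mean was 0.08. Interferon response genes had a mean of 0.38 (adjusted p = 0.605 with an estimated correlation), with differences of 1.38, -0.28 and -0.04 within the slides, so the direction did not hold within slides. Genes of mitosis and G2/M had a mean of -0.17 (adjusted p = 0.460 with an estimated correlation) and differences of -0.35, -0.27 and 0.11. Fibroblast and smooth muscle markers, of which 11 were bright enough to be tested, had a mean of -0.34 (adjusted p = 0.391 with an estimated correlation), differences of -0.41, -0.70 and 0.08 within the slides, and a mean of -0.18 without the second DMSO sample. The NRF2 targets of oxidative stress had a mean of 0.17, immediate early genes 0.19, metallothioneins -0.21, chaperones of the endoplasmic reticulum 0.13, autophagy and lysosome genes 0.09, p53 targets 0.14 and TGF-beta response genes -0.15. Their adjusted p-values were 0.427, 0.488, 0.430, 0.488, 0.512, 0.567 and 0.490 with an estimated correlation. Without the second DMSO sample these means were 0.05, 0.04, -0.07, 0.03, 0.02, 0.06 and -0.09, and of their members 1 passed over the list alone, AKR1B10 (log2 -1.03), an NRF2 target that was lower. The direction turned within slide 1 for metallothioneins (0.10) and within slide 3 for p53 targets (-0.03) and TGF-beta response genes (0.04). Cholesterol synthesis and uptake genes had a mean of -0.09 in MEHP and were not called (adjusted p = 0.0586), with differences of 0.04, -0.54 and 0.18 within slides 1, 2 and 3 and a mean of 0.05 without the second DMSO sample.

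The comparison of BDB with DMSO asked the same of another compound of the screen. Of 20893 genes 0 passed with limma, while 1662 (700 higher, 962 lower) had an unadjusted p under 0.05, where chance gives about 1045 on average. Other splits of the same BDB and DMSO arrays into 4 and 4 gave 348 to 2958 such genes, some more than the real split and others fewer. Splits with 2734 and 2586 put the slide 2 arrays on the same side, which the real split did not. The number above 1045 therefore does not show an effect of BDB, and it does not exclude such an effect. CPA4, a secreted carboxypeptidase, had the smallest p, with a log2 change of -1.52 ± 0.22 (n = 4 per group, adjusted p = 0.107). HHIP, a decoy receptor for hedgehog proteins, had -1.42 ± 0.24, EFEMP1, an extracellular matrix protein, -0.73 ± 0.13, and SH2D5 -0.61 ± 0.11 (adjusted p = 0.160 for each). With the same adjusted p, SLC25A15, the mitochondrial ornithine carrier, had -0.44, PRSS16 0.66 and TNFSF4 0.98, the last of these well above background on 2 of 4 DMSO arrays. RFLNA had -0.63 (adjusted p = 0.231), and COL12A1 -0.64 and the matrix protease MMP3 -1.88 (adjusted p = 0.344 for both), with MMP3 well above background on 3 of 4 BDB arrays. The 4 BDB arrays lay apart from the 4 DMSO arrays in 809 genes (3.87%), where chance gives 2.86% on average. Genes move together in these samples, so this share can also lie above 2.86% without an effect.

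Genes of cholesterol synthesis and uptake had a mean log2 value of -0.38 in BDB (interval -0.65 to -0.12, exact p = 0.0286), and their call was lost with an estimated correlation (adjusted p = 0.378). Of 26 genes 25 had a log2 value below 0, and 0 were lowered over all genes tested but 14 when adjusted over the list alone. Examples are INSIG1 (-0.89), which restrains sterol synthesis, LSS (-0.54), an enzyme of that synthesis, and HMGCS1 (-0.53 ± 0.20), an early enzyme of the mevalonate pathway. Within slides 1 and 2 the list's score differed by -0.18 and -0.83, with 0 BDB samples on slide 3, and without the second DMSO sample the mean was -0.24.

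PPAR targets had a mean of 0.22 in BDB (interval 0.11 to 0.33, exact p = 0.0286), and their call was lost with an estimated correlation (adjusted p = 0.2498). None of the 24 passed over all genes tested, and 6 were raised when adjusted over the list alone: ANGPTL4 (log2 1.18 ± 0.28, 2.26-fold, 95% interval 1.497 to 3.41), PDK4 (0.99), CPT1A (0.61), ECH1 (0.44), ACAA2 (0.43) and PLIN2 (0.37). With slide as a block the list's mean was 0.21, and the score differed by 0.24 and 0.14 within slides 1 and 2. Metallothioneins had a mean of -0.35 (adjusted p = 0.378 with an estimated correlation), with 0 of 10 lowered over all genes tested and 7 when adjusted over the list alone, among them MT1X (-0.47) and MT2A (-0.38). TGF-beta response genes had a mean of -0.29 (adjusted p = 0.378 with an estimated correlation), with 0 of 37 lowered over all genes tested and 4 when adjusted over the list alone: MMP3, PMEPA1 (-0.85), SPARC (-0.80) and COL4A2 (-0.48). Without the second DMSO sample the means of these lists were 0.20, -0.21 and -0.23.

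All 34 mitosis and G2/M genes had a log2 value below 0 in BDB, with a mean of -0.30 (adjusted p = 0.378 with an estimated correlation, exact p = 0.0857), and 0 passed over all genes tested or over the list alone. Within slides 1 and 2 the score differed by -0.37 and -0.47. Interferon response genes had a mean of 0.76 (adjusted p = 0.427 with an estimated correlation), 0 of 35 passed in either way, and within slides 1 and 2 the score differed by 1.31 and 0.94. The BDB arrays scored -0.57 to 0.95 and overlapped the DMSO arrays, at -0.90 to 0.10. Each difference within a slide rests on 1 DMSO array, at -0.90 on slide 1 and -0.73 on slide 2. The DMSO arrays of slide 3, which holds 0 BDB samples, scored 0.10 and -0.07. The amino acid response and ATF4 targets had a mean of 0.57 (adjusted p = 0.397 with an estimated correlation) that was 0.15 without the second DMSO sample. Immediate early genes had a mean of 0.31, p53 targets 0.28, genes of DNA replication -0.10, fibroblast and smooth muscle markers -0.42, chaperones of the endoplasmic reticulum 0.14, fatty acid synthesis genes -0.19 and reference genes -0.10. Their adjusted p-values were 0.391, 0.391, 0.567, 0.427, 0.537, 0.427 and 0.517 with an estimated correlation, 0 of their members passed over the list alone, and without the second DMSO sample the means were 0.16, 0.19, -0.13, -0.26, 0.04, -0.10 and -0.12. Other genes named in advance had log2 values of 0.87 for CYP1A1, 0.38 for CYP1B1, 0.65 for CDKN1A, -0.31 for MKI67, 0.84 for DDIT3 and 0.18 for HMOX1. In MKI67 the second BDB sample stood at 1.69 and the other BDB samples at 0.58 to 0.63, and without that sample the value was -0.58. In DDIT3, a stress transcription factor, the second DMSO sample stood at -0.81 against a mean of 1.83 in the others, and without it the BDB value was 0.18.

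The comparison of DOS with DMSO asked the same of the remaining compound. ANGPTL4 rose 4.22-fold (95% interval 2.80 to 6.37, log2 2.08 ± 0.28, n = 4 per group, adjusted p = 0.0431) and was the 1 gene of 20893 to pass with limma. An unadjusted p under 0.05 was reached by 699 genes. Within slides 1, 2 and 3 its log2 change was 1.57, 2.39 and 2.23, and with slide as a block it was 2.12 with an adjusted p of 0.0520, which did not pass. Leaving out any 1 of the 12 DMSO, MEHP or DOS arrays also ended this call. PDK4 had a log2 value of 1.27 ± 0.27 (2.41-fold, 1.63 to 3.57), APCDD1, an inhibitor of WNT signalling, -1.28 ± 0.32, SLC25A20 0.53 ± 0.13, ACAA2 0.51 ± 0.13 and WDFY1 0.55 ± 0.14, each with an adjusted p of 0.995. With that same adjusted p, RFLNA had -0.51, the readthrough gene ZNF664-RFLNA -0.53, COG5 0.34, UNC13D -0.76, CPT1A 0.58, PLIN2 0.23, MKI67 -0.40, HMGCS1 -0.21, HMOX1 0.05, CYP1A1 0.36, DDIT3 0.91 (0.25 without the second DMSO sample) and CDKN1A 0.27. CYP1B1 had -0.04 (adjusted p = 0.997), and its probes differed in sign.

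PPAR targets had a mean log2 change of 0.30 in DOS (interval 0.20 to 0.41, exact p = 0.0286), and their call was lost in camera with an estimated correlation (adjusted p = 0.110). ANGPTL4 and PDK4, the members with the largest changes, weigh most in that mean, so it is not the shift of a typical member. Of 24 genes 1 was raised over all genes tested, ANGPTL4, and 5 when adjusted over the list alone: ANGPTL4, PDK4, CPT1A, SLC25A20 and ACAA2. The list was called by fry (adjusted p = 0.0358), with a mean of 0.31 with slide as a block and score differences of 0.21, 0.35 and 0.38 within slides 1, 2 and 3. EHHADH, well above background on 1 of 4 DOS arrays, stood at -2.10 on the DOS array of slide 3, which raises the difference there. Genes of cholesterol synthesis and uptake had a mean of -0.26 (adjusted p = 0.378 with an estimated correlation), with 25 of 26 below 0 and 0 passing over all genes tested or over the list alone. The score of that list differed by 0.07, -0.73 and -0.20 within slides 1, 2 and 3, and without the second DMSO sample the mean was -0.12.

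**Figure D3:**
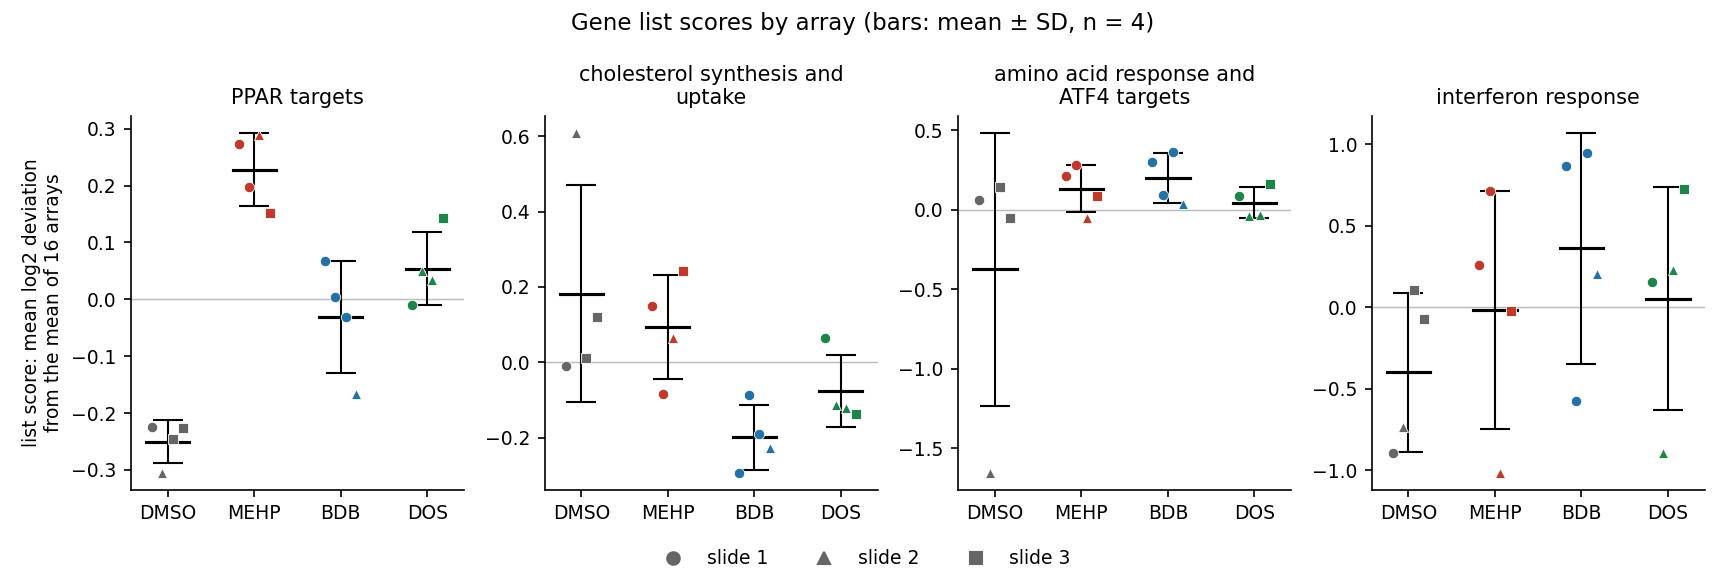
List scores (y axis, mean log2 signal of the list's genes, each gene centred over the 16 arrays) per array for 4 gene lists in DMSO, MEHP, BDB and DOS, with mean ± SD (n = 4). PPAR targets lay between -0.30 and -0.22 in DMSO and between 0.15 and 0.29 in MEHP, and 1 DMSO array lay at -1.65 for the amino acid response and ATF4 targets.

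The other 14 lists that camera called in DOS at the preset correlation did not keep the call with an estimated one. Mitosis and G2/M genes had a mean of -0.21 (adjusted p = 0.391 with an estimated correlation), with all 34 below 0, 0 passing, and differences of -0.09, -0.40 and -0.21 within the slides. The amino acid response and ATF4 targets had a mean of 0.42 (adjusted p = 0.485 with an estimated correlation), which became -0.01 without the second DMSO sample. Interferon response genes had 0.45 (adjusted p = 0.567 with an estimated correlation), with a range of 0.23 to 0.82 over the fits tried. Fibroblast and smooth muscle markers had -0.41, immediate early genes 0.22, TGF-beta response genes -0.19, p53 targets 0.19, hypoxia and glycolysis genes -0.13, metallothioneins -0.22 and androgen response genes -0.13. Their adjusted p-values were 0.378, 0.427, 0.391, 0.460, 0.391, 0.427 and 0.226 with an estimated correlation. Chaperones of the endoplasmic reticulum had 0.12, prostate basal epithelium markers -0.17, luminal markers -0.24 and heat shock genes -0.07, with adjusted p-values of 0.567, 0.378, 0.378 and 0.567 with an estimated correlation. Without the second DMSO sample the means of these 11 lists, in the same order, were -0.25, 0.07, -0.13, 0.10, -0.10, -0.07, -0.09, 0.02, -0.08, -0.08 and -0.07, and 0 of their members passed over the list alone. Within slide 1 the direction turned for TGF-beta response genes (0.04), metallothioneins (0.14) and heat shock genes (0.04).

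The remaining 12 lists were not called in any compound at the preset correlation, given here as the means in MEHP, BDB and DOS. Ribosomal proteins had 0.04, 0.02 and 0.01, oxidative phosphorylation 0.01, -0.04 and -0.02, peroxisome biogenesis 0.03, 0.04 and 0.04, and apoptosis regulators 0.03, 0.08 and 0.06. Steroid synthesis enzymes had -0.01, 0.03 and 0.01, the oestrogen response -0.22, -0.16 and -0.03, and xenobiotic metabolism genes, of which 6 were tested, -0.49, -0.23 and -0.21, with an adjusted p of 0.0511 in MEHP. LXR targets of cholesterol efflux had 0.02, -0.08 and -0.03, and NF-kB targets of inflammation -0.07, -0.11 and -0.06. Without the second DMSO sample these means were 0.19, 0.08 and 0.13 for LXR targets and 0.11, 0.07 and 0.12 for NF-kB targets, so most of their signs rest on that sample. Markers of cells that the line should not hold had -0.09, -0.17 and -0.06 for endothelium and -0.03, -0.03 and 0.07 for neuroendocrine cells, with 6 genes tested in each list. The mean, the median and the direction of the test differed in sign for neuroendocrine markers in all 3 compounds, for NF-kB targets in MEHP and DOS, and for ribosomal proteins, the oestrogen response and steroid synthesis in DOS. Leukocyte markers, of which 12 of 21 were tested, had -0.19, -0.25 and 0.06, and their scores were 0.28 or more on all 5 arrays of slide 2 and 0.01 or less on the other 11.

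The compounds were then compared directly at the same concentration and time. ANGPTL4 stood 7.40-fold higher in MEHP than in BDB (95% interval 4.91 to 11.2, log2 2.89 ± 0.28, n = 4 per group, adjusted p = 0.000671). SH2D5, which encodes an SH2 domain protein, stood 1.92-fold higher in MEHP (1.63 to 2.26, log2 0.94 ± 0.11, adjusted p = 0.00493), with differences of 1.03 and 0.60 within slides 1 and 2. These 2 genes passed with limma and 1023 had an unadjusted p under 0.05. Next came JPH3 (-0.68, adjusted p = 0.0501), the potassium channel KCNQ1 (-0.81, 0.0702), TNFSF4 (-1.08, 0.0950, well above background on 1 of 4 MEHP arrays), DHRS3 (-1.09), LTBP3 (-1.07) and COL12A1 (0.75), all 3 with 0.148, and IL11 (0.81, 0.270) and RAB3B (0.66, 0.278). With slide as a block 6 genes passed, and without the second DMSO sample, which is in neither group, 8 passed. With only the 2 groups compared 0 genes passed, with adjusted p-values of 0.199 for ANGPTL4 and 0.466 for SH2D5.

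PPAR targets stood higher in MEHP than in BDB by a mean of 0.26 (interval 0.15 to 0.37, exact p = 0.0286, adjusted p = 0.595 with an estimated correlation). Of 24 genes 1 was higher over all genes tested, and 4 were higher and 1 lower when adjusted over the list alone, among them PDK4 (1.02), SLC25A20 (0.67) and TXNIP (-0.59). The score differed by 0.22 and 0.45 within slides 1 and 2. ANGPTL4 and PDK4 had the largest differences and weigh most in the mean. Genes of cholesterol synthesis and uptake stood higher in MEHP than in BDB by 0.29 (interval 0.03 to 0.56, exact p = 0.0286, adjusted p = 0.842 with an estimated correlation), with 24 of 26 above 0, 0 passing, and 0.22 and 0.29 within slides 1 and 2. The mean of mitosis and G2/M genes was 0.13, of interferon response genes -0.38, of DNA replication genes 0.09, of p53 targets -0.13 and of fatty acid synthesis genes 0.16. TGF-beta response genes had 0.14, heat shock genes 0.09 and metallothioneins 0.14, and each of these 8 lists, called at the preset correlation, had an adjusted p of 0.941 with an estimated correlation. The direction turned within slide 1 for interferon response genes (0.07) and heat shock genes (-0.006) and within slide 2 for metallothioneins (-0.03).

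MEHP and DOS differed in 3 genes. ANGPTL4 stood 3.96-fold higher in MEHP (95% interval 2.63 to 5.98, log2 1.99 ± 0.28), CYP26A1 6.64-fold lower (3.75 to 11.8, log2 -2.73 ± 0.39) and DHRS3 2.51-fold lower (1.89 to 3.33, log2 -1.33 ± 0.19), each with n = 4 per group and a limma adjusted p of 0.0351. Within slides 1, 2 and 3 the log2 differences were 2.51, 1.73 and 1.53 for ANGPTL4, -3.22, -2.94 and -1.70 for CYP26A1 and -1.38, -1.61 and -1.47 for DHRS3. With slide as a block 1 of these passed, DHRS3, and in 11 of the 16 fits that left out 1 array 0 genes passed. An unadjusted p under 0.05 was reached by 551 genes. Among those that did not pass, NTF3 had 1.00 (adjusted p = 0.687), and SH2D5 0.52, TXNIP -0.72, FCMR 0.61, STRA6 -0.77, CD14 -1.15 and KAZALD1 -0.89 had adjusted p-values that rounded to 1.00.

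PPAR targets stood higher in MEHP than in DOS by 0.17 (interval 0.07 to 0.28, exact p = 0.0286, adjusted p = 0.595 with an estimated correlation). Of 24 genes 1 was higher over all genes tested, and 4 were higher and 1 lower when adjusted over the list alone. The score differed by 0.25, 0.25 and 0.01 within slides 1, 2 and 3. ANGPTL4 and PDK4 had the largest differences and weigh most in the mean. EHHADH, well above background on 1 of 4 DOS arrays, stood at -2.10 on the DOS array of slide 3 and at -5.04 on the MEHP array there. That dim gene lowers the difference within slide 3. Genes of cholesterol synthesis and uptake differed by 0.17, NRF2 targets by 0.08 and heat shock genes by 0.07 (adjusted p = 0.941 with an estimated correlation for each), and within slide 1 by -0.03, -0.12 and -0.10. Aryl hydrocarbon receptor targets differed by 0.16 (adjusted p = 0.595 with an estimated correlation), with 0 of 8 passing over all genes tested and 2 when adjusted over the list alone, CYP1B1 (0.71) and TIPARP (0.54).

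Between BDB and DOS 0 genes passed with limma, 673 had an unadjusted p under 0.05, and the smallest adjusted p was 0.977. The smallest p-values belonged to CPA4 (log2 -1.04), SLC25A15 (-0.38), EFEMP1 (-0.59), PRSS16 (0.54), OR2A9P (0.91, well above background on 3 of 4 DOS arrays), SLC5A10 (0.97), JPH3 (0.43), HHIP (-0.997), MYZAP (-0.56) and FST (-0.62). ANGPTL4 had -0.90 (interval -1.495 to -0.31), which did not pass over all genes tested or over the list alone (adjusted p = 0.133). PPAR targets differed by -0.09 (interval -0.19 to 0.02, exact p = 0.229), so neither equal nor unequal shifts are shown. At the preset correlation interferon response genes differed by 0.31, mitosis and G2/M genes by -0.09, ATF4 targets by 0.15, metallothioneins by -0.13, cholesterol synthesis and uptake by -0.12 and leukocyte markers by -0.30 (adjusted p = 0.941 with an estimated correlation for each). The leukocyte value was -0.10 with slide as a block.

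All 3 compounds were set against the same DMSO arrays, which makes their changes alike even without effects. ANGPTL4 was called in both MEHP and DOS, 0 genes were shared by the other pairs, and simulated groups without effects shared 0.02 to 0.05 genes on average. Log2 changes correlated across genes, which are not replicates, at 0.608 for MEHP and BDB, 0.606 for MEHP and DOS and 0.585 for BDB and DOS. Simulated groups without effects gave mean correlations of 0.548, 0.521 and 0.517. With the DMSO arrays split so that each compound had its own 2, the correlations were 0.065, -0.00038 and 0.037, and 0 genes were shared.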

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

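All tests of explanations in this part, and the counts of other splits, were chosen only after the results they test had been seen, as were the fits without slide 2. In 404 groups of 4 arrays (63 named genes, 34 list scores and 4 array measures in each group), the sample farthest out was compared with the spread of the rest. In 37 groups (9.16%) 1 array stood apart, where chance gives about 1 in 20 (5%). The array was the second DMSO sample in 16 of them, and the second BDB sample, the third MEHP sample and the first DOS sample in 5 each.

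In the second DMSO sample, log2 signals relative to the 75th percentile were -0.81 for DDIT3 (mean of the other 3 DMSO samples 1.83), -0.75 for ACSL1 (0.04), 0.94 for ACAA1 (1.06), -0.082 for COG5 (0.17), -3.61 for FCMR (-4.10), 2.05 for IMPA2 (1.68), 0.38 for LTBP3 (1.099) and 4.35 for UCP3 (3.60). Its list scores were -1.65 for the amino acid response and ATF4 targets, -0.25 for autophagy and lysosome, 0.51 for LXR targets, 0.36 for endothelial markers, 0.34 for fatty acid synthesis, -0.45 for NRF2 targets, -0.41 for p53 targets and 0.33 for the TGF-beta response. The first DOS sample stood at 0.99 for ACAA1, 5.39 for EFEMP1, 2.28 for ETFDH, -0.89 for SLC25A15 and 0.065 for the score of cholesterol synthesis and uptake. The second BDB sample stood at 1.24 for DDIT3, -0.22 for FST, 1.69 for MKI67, -4.49 for OR2A9P and 0.28 for the hypoxia score. The third MEHP sample stood at -0.12 for apoptosis regulators, -0.11 for chaperones of the endoplasmic reticulum, 0.34 for endothelial markers, 0.28 for leukocyte markers and 35.1 on the first principal component. The fourth BDB sample stood at -3.70 for MYZAP, the second MEHP sample at 2.06 for HADHA and -0.19 for the oestrogen response, the second DOS sample at -3.09 for KCNQ1 and 0.16 for xenobiotic metabolism, and the third DOS sample at 853 for the 75th percentile of signal.

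PPAR targets had higher mean scores in all 3 compounds than in DMSO, and in MEHP than in BDB and DOS, but with an estimated correlation the list passed for MEHP against DMSO alone (adjusted p = 0.0278), with adjusted p-values of 0.2498 for BDB, 0.110 for DOS and 0.595 for both differences between compounds. Slide as the cause of the shifts from DMSO is argued against by the 8 differences within slides, of which the lowest was 0.139, while MEHP and DOS differed by 0.01 within slide 3. The lowest array lay above the highest DMSO array by 0.377 in MEHP, 0.214 in DOS and 0.0585 in BDB, when the DMSO scores spanned 0.0804. So few DMSO scores measure their spread poorly, with an SD of 0.0376 against 0.0642 in MEHP and 0.0644 in DOS. The list had also already been seen to shift. Chance spread of the DMSO arrays is therefore not excluded for DOS or BDB, which did not pass with an estimated correlation. For MEHP, which passed, the gap argues against that spread as the whole cause. That the DMSO cultures were handled apart, as the note set2 in their titles could mean, cannot be told apart from the compounds for the smallest shift of 0.219, since every DMSO sample carries it, but it enters neither difference of MEHP from BDB and DOS, of which the smaller was 0.174. An effect of the compounds themselves stays open as a hypothesis.

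The amino acid response and ATF4 targets stood higher in all 3 compounds than in DMSO by 0.50 on average. Without the second DMSO sample a share of 0.148 of that shift was left (0.07), so a lower level of these genes in that 1 sample may be most of it. Slide is argued against, since the other 4 arrays of slide 2 scored at least 1.60 above that sample, and so is a compressed signal on its array, since a share of 0.967 of its score was left against genes of like brightness. Averaged over the 3 compounds, at most 0.445 of the shifts of the chaperone, immediate early and metallothionein lists was left without it, and at least 0.575 of those of the p53, fibroblast, TGF-beta, interferon, mitosis and PPAR lists, but single compounds departed from this: in BDB -0.21 of -0.35 was left for metallothioneins and 0.16 of 0.31 for immediate early genes, and in MEHP 0.06 of 0.14 for p53 targets. What made that sample differ, biological or technical, was not tested.

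Leukocyte markers were higher on all 5 arrays of slide 2, which hold samples of every group, by 0.69 within groups, with PTPRC at 1.505, NKG7 at 1.37 and ITGAM at 1.02. Leukocyte RNA as the whole source is argued against by 13 other abundant leukocyte transcripts. Their median difference was 0.08 (a share of 0.111 of the list's mean) against a median of 0.73 for the list, and their mean 0.21 against 0.69. Of these 13, S100A8, S100A9, HLA-DRA, CD37 and CD53 were not well above background on any of the 5 arrays. The differences of dim transcripts carry little weight, but the 5 that were well above background on all 5 arrays had a median difference of 0.04 (SD over genes 0.30), with ARHGDIB 0.69 higher and the other 4 between -0.06 and 0.15. A compressed dim signal on slide 2, where the dimmest genes deviated by 0.19 to 0.33 and elsewhere by -0.21 to -0.03, is argued against as the whole cause, since a share of 0.781 of the difference was left against genes of like brightness. No biological explanation was tested, since the groups do not follow the slides, and what differed on slide 2 stays open.

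Each comparison's 8 arrays can be split into 4 and 4 in 35 ways. For genes changed by MEHP, 1 of the 35 splits gave as many, the real one with 6 against 1 at most in the others. This is the smallest share that 35 splits can give, and it was not adjusted over the 6 comparisons, so the split count alone does not exclude chance. The same share was reached for DOS (1 of 35 splits, 1 gene against 0), for MEHP and BDB (1 of 35, 2 genes against 1) and for MEHP and DOS (1 of 35, 3 genes against 1), by margins of 1 or 2 genes. Chance is not excluded for these either, and the splits took no account of slide. These counts fell in other fits, among them for MEHP to 1 with only the 2 groups compared or without DMSO replicate 1, for DOS to 0 with slide as a block or without any 1 of 12 arrays, between MEHP and BDB to 0 with only the 2 groups compared, and between MEHP and DOS to 0 without any 1 of 11 arrays. The log2 change of ANGPTL4 stayed between 1.66 and 2.17 for DOS (2.08 ± 0.28, and 2.12 ± 0.27 with slide as a block, adjusted p = 0.0520), between 2.57 and 3.11 for MEHP and BDB and between 1.86 and 2.11 for MEHP and DOS over all the fits tried, so its size changed little to moderately where those calls ended. A count of 0 genes, as for BDB and for BDB against DOS, is reached by 35 of 35 splits whatever the data and says nothing about chance. For BDB 1 split gave 6 genes, with the second BDB sample among the DMSO samples and the third DMSO sample among the BDB samples. A regrouping of arrays can thus also call genes, and what made that split differ was not tested. For BDB against DOS the other splits gave 0 genes. For gene lists adjusted within a comparison, as many were given by 3 of 35 splits for MEHP (16 lists, others up to 17), 8 for BDB (14, others up to 17) and 4 for DOS (16, others up to 19). The counts were 28 of 35 for MEHP and DOS (4, others up to 17) and 26 for BDB and DOS (6, others up to 16), so chance cannot be excluded for these list counts. The 2 other splits that reached the MEHP count put the slide 2 arrays on the same side, while the PPAR shift with slide as a block was 0.48. For MEHP and BDB 1 of 35 splits gave as many lists (15 against 14), a margin of 1 list, and with an estimated correlation 0 lists differed (lowest adjusted p 0.595), so that count is not taken to exclude chance.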

How the results depend on the processing

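The fits without slide 2 and those without the second DMSO sample with a slide block were chosen after seeing the data, and all others were planned. With an estimated correlation, gene list shifts fell from 45 to 1 against DMSO and from 21 to 0 between compounds, because genes of a list move together in these samples. Genes changed by MEHP against DMSO were 3 with the median in place of the 75th percentile, 3 with no filter on dim probes (more genes tested), 10 with slide as a fixed block, 3 with a replicate block, 1 with only the 2 groups compared (fewer samples), 116 with array weights, 340 at an unadjusted p under 0.05 with 1.5-fold, and 2 without slide 2 (1 of the 6). Genes changed by BDB were 1 with normexp background correction, 1 with the median, 1 with an intensity trend and robust variances, 7 with array weights and 521 at an unadjusted p with 1.5-fold. Genes changed by DOS were 0 with quantile normalization, no filter, slide as a fixed block, a replicate block, without slide 2, and without DMSO replicate 2 with slide as a fixed block, and 156 at an unadjusted p with 1.5-fold. Genes that differ between MEHP and BDB were 6 with slide as a fixed block, 7 with slide as a random block, 0 with only the 2 groups compared, 88 with array weights, 318 at an unadjusted p with 1.5-fold, 4 without slide 2 and 7 without DMSO replicate 2 with slide as a block. Between MEHP and DOS they were 0 with no filter, 1 with slide as a fixed block, 0 with a replicate block, 1 with only the 2 groups compared, 3446 with array weights, 144 at an unadjusted p with 1.5-fold, 0 without slide 2 and 11 without DMSO replicate 2 with slide as a block. Between BDB and DOS they were 1 with no filter and 192 at an unadjusted p with 1.5-fold, and list shifts between compounds were 12 with quantile normalization. With the controls split 2 and 2 the correlations were 0.0653 for MEHP and BDB, -0.000379 for MEHP and DOS and 0.0373 for BDB and DOS, because the shared arrays then drop out. The overlap of changed genes between MEHP and DOS was 0 with that split, with quantile normalization, with no filter and with slide as a fixed block. PPAR targets, cholesterol synthesis and uptake, mitosis and G2/M, interferon response and ATF4 targets were followed through every fit, and in 2 of these lists the shift reversed. Of the other lists, some turned without DMSO replicate 2, among them NF-kB targets, LXR targets in BDB and DOS, and fatty acid synthesis in MEHP. The amino acid response and ATF4 targets in DOS ranged from -0.00664 to 0.591 as each array was left out, the lowest without DMSO replicate 2, whose low score shows the cause, and cholesterol synthesis and uptake in MEHP, not called, was 0.0832 without that sample and with slide as a block, 0.0524 without it alone, 0.0496 with array weights and 0.0620 without slide 2, while 9 of its 32 alternatives called it lower. Unless named here, the cause was not tested. Leaving out each array gave 1 to 7 genes for MEHP (1 without DMSO replicate 1, 2 without MEHP replicate 1, 3 without MEHP replicate 2 or 3), 0 to 2 for BDB (2 without DMSO replicate 3, 1 without MEHP replicate 2 or BDB replicate 4), 0 to 1 for DOS (0 without any DMSO, MEHP or DOS array), 2 to 8 for MEHP and BDB (8 without DMSO replicate 2, 4 without BDB replicate 3), 0 to 5 for MEHP and DOS (5 without DMSO replicate 2, 1 without MEHP replicate 4 or BDB replicate 1 or 2, 0 without 11 others) and 0 to 0 for BDB and DOS. It gave 41 to 49 list shifts against DMSO, 10 to 33 between compounds (10 without MEHP replicate 4, 33 without DMSO replicate 2), and correlations of 0.477 to 0.722, 0.469 to 0.734 and 0.395 to 0.708. Over 13 alternatives set in advance and the 16 fits with 1 array left out, ANGPTL4 in MEHP passed in 13 and 16, PDK4 and SLC25A20 in 11 and 14, CYP26A1 in 11 and 12, ACADVL in 8 and 2, and PLIN2 in 5 and 2. ANGPTL4 in DOS passed in 9 and 4, ANGPTL4 and SH2D5 between MEHP and BDB in 12 and 16, and ANGPTL4, CYP26A1 and DHRS3 between MEHP and DOS in 10, 9 and 9 and in 4, 2 and 2. None of these 12 called results reversed in 372 values, 236 of which stayed past the threshold. The call of PPAR targets in MEHP with an estimated correlation held in 11 of those 13 (adjusted p 0.00957 to 0.344) and in 9 of the 16 left-out fits (0.00159 to 0.153). Whether same-number samples were paired cannot be told, since slide differences were left in the values correlated. Of 16 arrays 5 were closest to their own number. Of 24 pairs 10 correlated at over 0.1, among them all 6 pairs of replicate 1 (0.192 to 0.427), whose 4 arrays shared slide 1. The third MEHP and DOS samples, both on slide 2, correlated at 0.617, and the second ones, on slides 1 and 2, at -0.394. Probes under background limit dim genes such as TNFSF4 and MMP3.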

Other observations

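The test of retinoid genes in this part was chosen only after the results had been seen. CYP26A1 and DHRS3, both lower in MEHP than in DOS, are known to be induced by retinoic acid and to remove retinoic acid or its precursor. This led to the hypothesis that retinoid signalling was lower in MEHP. To test it, 27 other retinoid-responsive genes were written down, of which 21 were bright enough. Among these, STRA6 had already been named above as lower in MEHP than in DOS (log2 -0.77), without passing. It is therefore no independent evidence in that comparison, and the list was not tested without it. In MEHP 19 of the 21 were lower than in DMSO, with a mean log2 change of -0.37 (p = 0.000943 with an estimated correlation, 0.00490 adjusted over 6 comparisons). The score gave an exact p of 0.0286, the smallest possible, and 1 gene was lowered when adjusted over the list alone, MEIS2 (log2 -0.57), and 0 over all genes tested. Against DOS 18 of the 21 were lower, with a mean of -0.28 and an adjusted p of 0.00490. Adjusted over the list alone 4 were lower, among them STRA6 (-0.77), which takes retinol into cells, RARRES1 (-0.65) and MEIS2 (-0.40). The mean was -0.22 against BDB (adjusted p = 0.0297), while BDB and DOS had means of -0.15 and -0.10 against DMSO (adjusted p = 0.373 and 0.535).

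The scores of these genes in MEHP differed from DMSO by -0.27, -0.66 and -0.27 within slides 1, 2 and 3, and from DOS by -0.37, -0.16 and -0.27. The second DMSO sample scored 0.54 and the other DMSO samples between 0.01 and 0.05. Without it the mean change in MEHP was -0.246 (p = 0.000204 with an estimated correlation), and the difference from DOS, in which no DMSO sample enters, was -0.277. Lower retinoid signalling in MEHP is a hypothesis that these values fit, found and tested on the same samples, and it may have other causes than the compound's action on retinoid receptors, none of which was tested. STRA6 has probes that differ in sign for MEHP and BDB against DMSO.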
